A study of Arabidopsis thaliana with 18 samples.

How the data were processed

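RNA of Arabidopsis thaliana Col-0 and flk was hybridised to ATH1 arrays, with 6 groups of 3 arrays from 3 experiments that differed in age, light regime and hour of collection, per the labels. The deposited values were probe-set intensities on a linear scale, 1 table for the 18 arrays. The summary method, background correction and scaling used by the authors were not given in the sources used here. From the values themselves, arrays of one experiment had nearly equal distributions and the experiments did not, so the deposited intensities appeared to be scaled within and not across experiments. Among the 153 pairs of arrays, 0 held identical values.

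Of 22810 probe sets, the 64 array controls were left out and 22746 were tested with no filter on dim probe sets. The 10th percentile of all values, 8.29, was added as a pseudocount before taking log2. Array medians then ranged from 4.80 to 6.17, more than the 0.5 log2 units allowed by a rule set before the data were examined, so the log2 values were quantile-normalized over all arrays, and the deposited scaling became an alternative. Quantile normalization sets all arrays to one distribution and so removes any shift of most genes between experiments. Fold changes are on the log2(value + pseudocount) scale and can differ from ratios of the deposited intensities. The absent bacterial controls reached 8.36, 11.3 and 10.1 in the 16-day long-day, continuous-light and 7-day experiments, and levels near these carry little signal. In continuous light 49.9% of values were under 20, against 32.9% in 16-day long days, on deposited scales that differ. Array medians of 19.6 to 21.7 there lay nearer to the absent controls than those of 61.8 to 63.9 in 16-day long days. This weak signal limited what could be seen in continuous light.

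Groups were taken from the labels. One limma fit of 6 group means with 12 residual degrees of freedom, an intensity trend in the variance prior and Benjamini-Hochberg adjustment over 22746 probe sets gave the flk effect in each experiment, its average with equal weights, an F test of its differences among experiments and the 2 comparisons within Col-0. This fit assumes 1 spread for every array of a probe set, and the spread was unequal: 0.213 log2 units in continuous light and 0.0636 in 16-day long days after quantile normalization, and 0.165 and 0.0743 as deposited. Each experiment was therefore also fitted alone, as had been planned, and both counts stand beside each other. Gene lists with at least 4 measured genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, 1 probe set per gene with the highest mean level. Of 21 lists fixed before the data were examined, 2 had enough measured genes, since 30 of 242 list genes had a probe set paired with them alone.

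Gene names came from the platform annotation given with the data. A single gene was paired with 13513 probe sets (59.4%), several with 503 and none here with 8730. Symbols were updated through Entrez identifiers to the RefSeq annotation of assembly TAIR10.1, where 13436 of the single-gene probe sets had an entry. The genome build behind the deposited values was not given in the sources used here, and no coordinates are printed.

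Named genes followed a rule written before the data were examined: per flk comparison the 5 largest rises and 5 largest falls past the threshold whose flk and Col-0 arrays did not overlap, 10 and 10 for the average among probe sets with the same sign in each experiment, the 6 smallest p for the differences, 5 and 5 for each comparison within Col-0, all members of the floral repressor and floral integrator lists, and up to 4 members of every other list. Probe sets naming no gene or several were passed over, among rises and falls 7 and 12 in 16-day long days, 2 and 6 in continuous light, 3 and 5 in 7-day long days, 3 and 6 for the average, 22 and 8 for age and hour and 9 and 12 for light. The unnamed probe sets and AT3G47250 were singled out after their values were seen, as probe sets called in every experiment.

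The procedure was tested on simulated data with the real means, 22746 probe sets and 200 of them changed. With each experiment's own spread, the shared fit recovered 79% of changes of 0.5 log2 units and 100% of changes of 1 in 16-day long days, 83% and 99% in continuous light and 73% and 98% in 7-day long days. Unchanged probe sets made up 1.65%, 82.5% and 8.06% of the calls, and in fits of each experiment alone 0.995%, 1.18% and 6.12%. These shares depend on the 200 changed probe sets and the independent noise set in the simulation and do not carry over to the real calls. Alone, continuous light recovered 18% and 66%. Camera called a shifted list of 4 genes for the average flk effect and gave p under 0.05 for 10 of 200 unshifted lists. These lists were random, with independent noise and 1 spread per probe set over all experiments. The check therefore says nothing about lists of correlated genes or about unequal spread.

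Alternatives set beforehand were 2 other pseudocounts (2nd and 25th percentiles), the deposited scaling, median centring, filters on dim probe sets at the 25th and 50th percentiles, the replicate number as a block, each experiment alone, array weights, a prior without an intensity trend, other thresholds (adjusted p under 0.01, or a change of at least 2-fold) and leaving out each array. Weights per experiment and an average over the long-day experiments were added after the data were seen. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for plots.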

Results

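Transcript levels were measured on 18 ATH1 GeneChip arrays, a 1-colour Arabidopsis array with 22810 probe sets, in total RNA of wild-type Col-0 and of the flk mutant. FLK encodes a KH-domain RNA-binding protein that promotes flowering through the autonomous pathway. Each genotype was profiled in 3 experiments with 3 arrays per group: 16-day-old long-day plants collected 16 h after dawn, 16-day-old plants in continuous light with no hour named, and 7-day-old long-day plants collected 1 h after dawn. The labels did not name the tissue. Median intensities were 61.8 to 63.9 in 16-day long days, 19.6 to 21.7 in continuous light and 34.6 to 38.1 in 7-day long days, and the number of arrays limited the precision. Levels below are deposited intensities as mean ± SD with n = 3. Log2 changes are flk minus Col-0 on the log2(value + 8.29) scale after quantile normalization. The added 8.29 shrinks changes of weakly expressed genes, but quantile normalization can enlarge them. Printed changes can therefore lie below the ratio of the intensities or, as for AT4G31470 in continuous light, above it. The deposited scale differed between experiments, so intensities of different experiments do not share one scale. A gene was called where limma's Benjamini-Hochberg adjusted p was under 0.05. The labels did not say that replicates were separate plants or harvests, so the p-values measure the spread between these arrays, which may be technical. No probe set was paired with FLK here, so the mutated gene could not be identified in the arrays. It may be among the probe sets without a paired gene.

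Which transcripts changed in flk under every condition was examined first. The probe set 250476_at, which has no gene paired with it here, was higher in all flk arrays than in the Col-0 arrays of the same experiment, by 2.15 ± 0.0782 (SE) log2 units in 16-day long days, 2.94 in continuous light and 2.44 in 7-day long days. Its intensity was 162 ± 4.26 against 19.9 ± 2.26 in Col-0, 270 ± 30.5 against 25.1 ± 2.38, and 891 ± 6.99 against 146 ± 14.6 in that order. The unnamed probe set 258790_at fell, with changes of -2.65, -2.42 and -3.04, from 295 ± 14.9, 64.1 ± 23.4 and 202 ± 11.1 in Col-0 to 36.3 ± 4.34, 13.0 ± 2.38 and 12.1 ± 0.886 in flk, and the last 2 levels lay close to the highest absent-control intensities of 11.3 and 10.1. Among named genes, AT5G06770 and AT3G51180, both encoding CCCH zinc-finger proteins, rose in each experiment, AT5G06770 by 0.91, 0.90 and 0.70 and AT3G51180 by 0.96, 0.77 and 1.09. AT3G60980, AT3G32940, AT1G76020 and AT3G47250 fell in each experiment, with average changes of -0.72, -0.57, -0.60 and -0.40. In all, 12 probe sets were called in the same direction in the 3 experiments, 4 higher and 8 lower, against 0.119 for independent lists, and 6 of them named a single gene. The lists were not independent, since the shared fit used 1 estimate of spread per probe set in all 3 experiments. The unnamed 246550_at rose by 0.43 to 0.55 and 261041_at had changes of -1.11, -0.48 and -0.67. Fitted on each experiment alone, 4 probe sets met this criterion and 2 did under both fits, 250476_at and 258790_at; none of the 6 named genes was called in continuous light alone, where AT5G06770 had adjusted p = 0.0605 and AT3G60980 0.0550. The count of 12 was 5 to 7 without 1 of Col-0 replicates 2 and 3 or flk replicates 1 and 3 of the 7-day experiment, and 23 and 24 without Col-0 replicate 1 or 2 of continuous light.

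**Figure D1:**
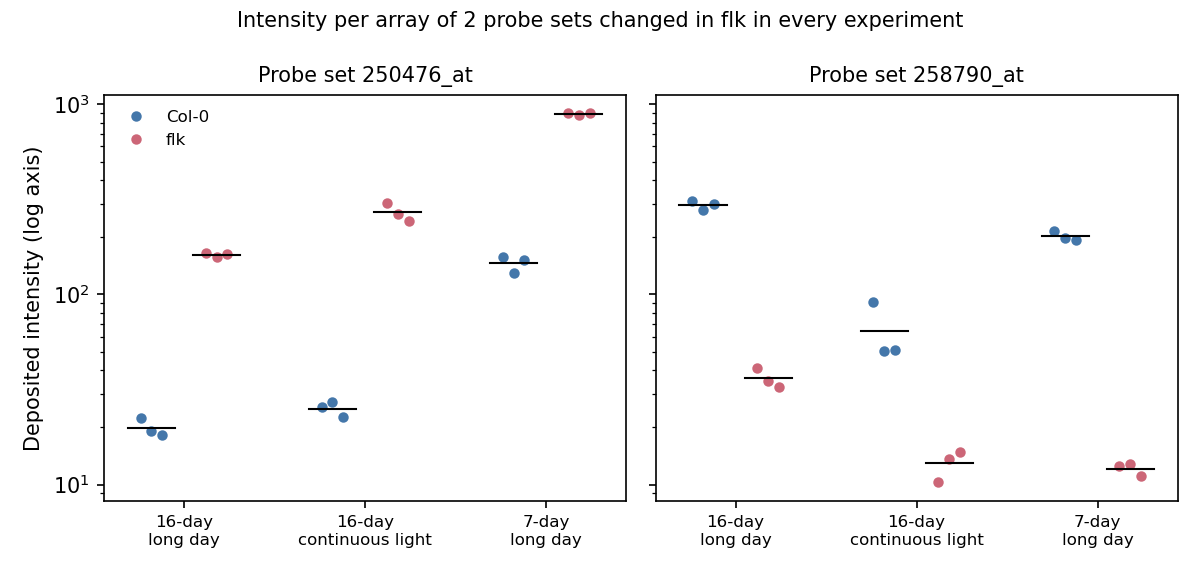
Deposited intensity per array (log axis) of the unnamed probe sets 250476_at and 258790_at in the 3 experiments, with 3 Col-0 arrays in blue, 3 flk arrays in red and a bar at each group mean. In every experiment the flk arrays lie above all Col-0 arrays for 250476_at and below them for 258790_at.

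In 16-day long-day plants collected 16 h after dawn, COR15A, a cold-regulated chloroplast protein gene, rose in flk by 1.55 ± 0.118 (SE) log2 units, from 313 ± 6.08 in Col-0 to 810 ± 53.2 (adjusted p = 2.0e-07), and the cold-regulated COR15B and COR47 rose by 1.07 and 0.41. The plastid-encoded rps14 and rpoB rose by 1.51 and 1.31, and the peroxidase genes AT4G26010 and AT5G17820 by 1.42 and 1.19. JRG21, a jasmonate-responsive oxygenase gene, fell by 2.15 log2 units, from 222 ± 27.9 to 38.1 ± 3.96 (adjusted p = 1.0e-05), and the related oxygenase gene AT5G05600 fell by 1.42. The peroxidase gene PRX52 fell from 295 ± 23.7 to 66.6 ± 1.93, a change of -2.09, the osmotin-like OSM34 from 1679 ± 20.4 to 639 ± 42.9, and AT1G62760 from 167 ± 7.77 to 37.5 ± 3.29. These were the 5 largest rises and falls among probe sets with a single gene, and all 10 were also called with this experiment fitted alone. The root marker EXPA18 rose by 0.61 and EXPA7 had a change of 0.53 (adjusted p = 0.0543), while the root marker PYK10 had 3892 ± 288 in flk and 3893 ± 81.6 in Col-0. The call of EXPA18 ended on leaving out any 1 of the 6 arrays.

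In that experiment 1024 of 22746 probe sets were called, 407 higher and 617 lower, and 70 of them changed at least 2-fold. The replicate spread was 0.0636 log2 units here against 0.213 in continuous light and 0.0934 in 7-day long days, or 0.0743, 0.165 and 0.102 under the deposited scaling, and a fit of this experiment alone called 4771, including all 1024. The count was 630 to 670 without any 1 of its 6 arrays.

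In 16-day plants in continuous light, GI, a clock-associated gene of the photoperiod pathway, fell by 1.19 log2 units in flk, from 86.6 ± 4.05 to 36.7 ± 3.01 (adjusted p = 1.3e-07, and 0.00394 for this experiment alone). AT1G67865 fell from 206 ± 40.0 to 66.5 ± 11.6, AT1G70820 from 520 ± 57.4 to 216 ± 26.6 and AT2G29670 from 396 ± 29.8 to 187 ± 17.9. AT5G03350 rose by 1.32 log2 units, from 120 ± 19.0 to 365 ± 59.1, and AT1G06000 by 1.16, from 51.3 ± 0.679 to 144 ± 15.7. AT1G13650 rose from 41.3 ± 5.61 to 128 ± 42.4 and AT3G15310 from 11.7 ± 2.297 to 30.8 ± 12.02. The defensin gene PDF1.2 changed by 1.79 (198 ± 114 against 40.1 ± 16.8) and AT4G31470 by -1.02 (14.3 ± 2.72 against 25.3 ± 5.32), and these alone of the 10 genes lost their call when the experiment was fitted by itself (adjusted p = 0.0816 and 0.141).

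Over all probe sets, 2645 were called in continuous light with the spread shared over the 18 arrays, 1471 higher and 1174 lower, or 55.6% higher. Fitted alone, the experiment gave 114 calls, 52 higher and 62 lower, all of them among the 2645. Data were also simulated with each experiment's own spread and with noise independent between probe sets. There the shared fit called 860 unchanged probe sets among 1042 in continuous light and the fit alone 1 among 85. Higher calls made up 74.7% under the deposited scaling and 74.98% with arrays centred on their medians. The actin 3'/5' ratio, a sign of RNA quality, ranged widely among these arrays, at 1.77 ± 0.687 log2 units in Col-0 and 2.05 ± 0.289 in flk, and the shared fit called 5457 without Col-0 replicate 1, which had 2.57, and 1773 without flk replicate 1, which had 2.38.

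**Figure D2:**
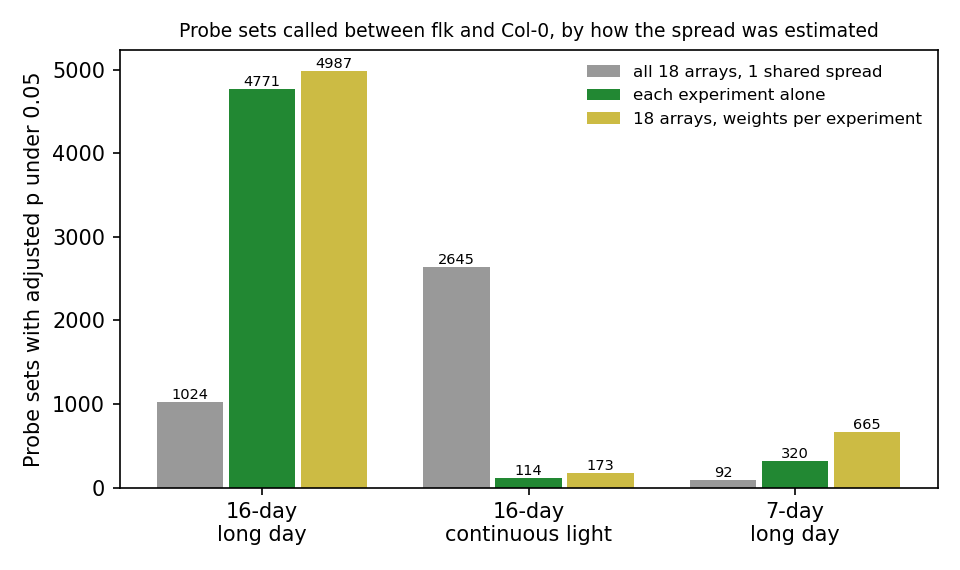
Number of probe sets with adjusted p under 0.05 between flk and Col-0 (bars from 0) in the 3 experiments, with the spread shared over 18 arrays, with each experiment fitted alone, and with a weight per experiment. Continuous light gave 2645 calls with the shared spread and 114 alone, and 16-day long days 1024 and 4771.

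In 7-day long-day seedlings collected 1 h after dawn, AT1G66100 rose by 0.92 ± 0.0603 (SE) log2 units in flk, from 1152 ± 37 to 2231 ± 146 (adjusted p = 8.4e-08). The zinc-finger gene AT3G51180 rose from 25.01 ± 3.07 to 74.6 ± 2.46, AT3G28220 from 258 ± 44.8 to 437 ± 54.8, AT5G06770 from 61.0 ± 6.45 to 116 ± 10.6 and AT3G15310 from 8.89 ± 0.298, an absent-control level, to 20.4 ± 4.08. AT1G20390 fell from 56.8 ± 6.14 to 19.5 ± 1.25, AT2G36430 from 162 ± 20.4 to 78.7 ± 0.855, and AT3G60980 from 76.7 ± 5.82 to 40.0 ± 1.51. THIC, an enzyme gene of thiamine synthesis, fell by 0.61 log2 units, from 660 ± 13.1 to 425 ± 22.6, and AtLEA4-1 had 23.55 ± 6.22 against 44.4 ± 9.15, a change of -0.64. Fitted alone, this experiment called 9 of these 10 genes and not AtLEA4-1 (adjusted p = 0.0733), and the calls of AT3G51180, AT1G20390 and AT3G15310 ended in the shared fit on leaving out any 1 of its 6 arrays. In all, 92 probe sets were called, 42 higher and 50 lower, or 45.7% higher, against 56.4% under the deposited scaling, and 4 changed at least 2-fold. The fit of this experiment alone called 320, with 78 of the 92 among them. Without Col-0 replicate 1, 2 or 3 or flk replicate 1 or 3 of this experiment, or flk replicate 1 of 16-day long days, the count was 29 to 60, and without Col-0 replicate 1, 2 or 3 of continuous light it was 139 to 216.

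Averaged over the 3 experiments, the zinc-finger genes AT3G51180 and AT5G06770 were higher in flk by 0.94 ± 0.118 and 0.84 ± 0.0547 (SE) log2 units, and AT3G15310 was called higher too, with no size given since its Col-0 level in 7-day long days was that of absent controls. The defensin genes PDF1.2 and PDF1.2b were higher by 1.16 ± 0.231 and 0.71 ± 0.154. AT1G13650, AT3G28220 and the peroxidase gene AT5G64100 rose by 0.61, 0.61 and 0.63, and the plastid-encoded rps14 and petD by 0.61 each. The jasmonate-related oxygenase genes JRG21 and AT2G38240 had average changes of -0.98 and -0.73, AT1G67865 of -0.87, AT3G60980 of -0.72, and AT1G76020, AT1G73600, SAG29, AT3G32940 and AT1G20390 between -0.60 and -0.57. The same sign of change in the 3 experiments was required for naming these 20 genes, and the size differed among experiments for rps14, JRG21, AT1G13650, AT1G67865, petD and AT3G28220 (adjusted p of the difference 0.000374 to 0.0252). In the order of the experiments, rps14 changed by 1.51, 0.22 and 0.12 and JRG21 by -2.15, -0.74 and -0.05. PRX52, the last of the 20, changed by -2.09 in 16-day long days and lay at absent-control level in both genotypes in the other two experiments, so neither its change there nor an average could be measured. The average effect was called for 1264 probe sets, 609 higher and 655 lower, of which 3 changed at least 2-fold. In simulated data with each experiment's own spread and independent noise, 20% of the calls of this average were unchanged probe sets. With 1 spread for all experiments it was already 10.3%, so unequal spread did not account for the whole share. The long-day experiments alone, an average chosen after the data were seen, called 3240. The count was 2741 without Col-0 replicate 1 and 1930 without Col-0 replicate 3 of continuous light.

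The flk effect was then compared among the experiments by a test of the differences themselves. GI rose by 0.62 log2 units in flk in 16-day long days, from 389 ± 10.7 to 558 ± 9.84, but fell by 1.19 in continuous light, and had 72.3 ± 9.05 against 80.2 ± 6.63 in 7-day long days (adjusted p of the difference 1.0e-07). The thionin gene THI2.2 rose by 1.16 in 16-day long days and by 0.53 in 7-day long days and changed by -0.34 in continuous light (adjusted p of the difference 3.0e-09), a change that was not called in that experiment alone (adjusted p = 0.106). AT5G62720 rose by 0.63 in 16-day long days, from 295 ± 10.5 to 432 ± 7.71, and fell in continuous light and 7-day long days, with changes of -0.84 and -0.55. AT1G62760 fell in 16-day long days and had a change of 0.14 in continuous light. PRX52 fell in 16-day long days, but flk and Col-0 lay under the highest absent-control intensity in continuous light, at 9.39 ± 1.08 and 10.1 ± 0.537, and in 7-day long days, at 9.05 ± 0.359 and 9.62 ± 0.468, so a fall there could not have been seen. AT1G66100 had changes of -0.31, -0.01 and 0.92 in the order of the experiments. These had the 6 smallest p-values among single-gene probe sets.

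In all, the effect differed among the experiments for 1512 probe sets at an adjusted p under 0.05. Between 16-day long days and continuous light it differed for 1447, between the long-day ages for 363 and between continuous light and 7-day long days for 611. Simulated data with no difference and each experiment's own spread gave 37 false calls with the shared spread and 7 with a weight per experiment. The simulated noise was independent between probe sets, so these counts set no background for the real ones. Regrouping the real arrays within experiments, which breaks up the flk effect, gave up to 1064 calls with the shared spread. With such weights, chosen after the data were seen, the real data gave 566 calls, and without Col-0 replicate 1 of continuous light the shared fit gave 3634.

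**Figure D3:**
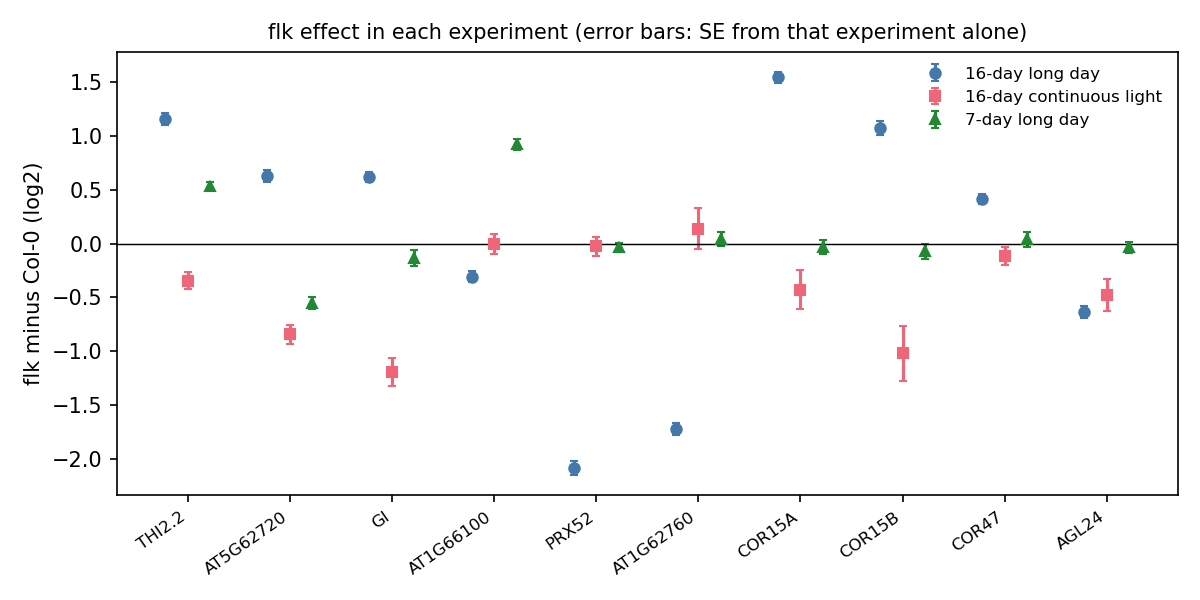
Change of 10 genes in flk (flk minus Col-0, log2) in 16-day long days (circles), 16-day continuous light (squares) and 7-day long days (triangles), from 3 arrays per group, with error bars of 1 SE from that experiment fitted alone. GI rises by 0.62 in 16-day long days and falls by 1.19 in continuous light, COR15A rises by 1.55 in 16-day long days, and the PRX52 points of the other two experiments are at absent-control levels.

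The calls of the experiments were set against each other. Called in both 16-day experiments were 122 probe sets with the same direction and 143 with opposite directions, against 58.2 and 60.9 for independent lists, and across probe sets, which are not independent replicates, the changes had r = 0.034. The 16-day and 7-day long-day experiments shared 27 calls of the same direction and 7 of opposite direction, against 2.11 and 2.03, and continuous light and 7-day long days 29 and 6, against 5.30 and 5.40. With each experiment fitted alone, the 16-day experiments shared 18 calls of the same and 45 of opposite direction, against 11.97 and 11.9. The experiments had no arrays in common.

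Gene lists fixed from flowering, clock, hormone, stress and organ biology were followed next. In the cold and abscisic acid list, 3 of 13 genes were measured, and COR15A, COR15B and COR47 all rose in 16-day long days. In continuous light COR15A changed by -0.43 (34.0 ± 5.22 against 43.9 ± 9.46) and COR15B by -1.02 (50.8 ± 11.4 against 114 ± 55.2), both called with the shared spread and not in that experiment alone (adjusted p = 0.460 and 0.150), and none was called in 7-day long days, where COR15A and COR15B lay close to the absent controls. In the list of flavonoid and anthocyanin synthesis, 4 of 13 genes were measured, and in 16-day long days UF3GT, an anthocyanin glycosyltransferase gene, had a change of -0.59 (446 ± 5.47 against 646 ± 11.6, adjusted p = 0.0458), which ended on leaving out any 1 of the 6 arrays. UGT75C1, DFR and 5MAT had changes of -0.45, -0.42 and -0.37 in 16-day long days with adjusted p = 0.0657, 0.128 and 0.505, and 3 of the 4 members were called when adjusted over the list alone. This was the 1 pair of list and comparison among 8 past the threshold in limma's camera (adjusted p = 0.000846), and it was lost with an estimated correlation (adjusted p = 0.274 with an estimated correlation). In the floral integrator list, 4 of 15 genes were measured, and AGL24, a MADS-box gene that promotes flowering, fell by 0.63 log2 units in 16-day long days, from 68.4 ± 3.73 to 33.6 ± 1.93. In continuous light AGL24 had 12.1 ± 0.465 against 15.9 ± 1.09, called with the shared spread but not alone (adjusted p = 0.284), and in 7-day long days 11.2 ± 0.314 against 11.7 ± 1.02, close to the absent controls. AGL42, FD and AGL19 were called in no flk comparison, with AGL42 and AGL19 at absent-control level outside 16-day long days, and camera gave this list adjusted p = 0.241 in 16-day long days and 0.354 in continuous light. The directional test fry, which asks whether a list's genes moved one way and not whether they differed from other genes, gave it adjusted p = 0.000943 and 0.00246. The list median was only -0.02 and -0.05 in these comparisons, and of the 4 genes AGL24 alone was called. These values therefore do not show a joint fall of the list.

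Of the photoperiod list, GI and CDF5, a repressor of the photoperiod gene CO, were measured, and CDF5 had an average change of -0.30 ± 0.0592 (SE). GI, with an average of -0.23 that turned to 0.25 over the long-day experiments alone, was also the 1 measured gene of the evening clock list, and none of the morning clock list was measured. LUMINIDEPENDENS (LD) of the autonomous pathway list was higher in continuous light by 0.51 with the shared spread and not called alone (adjusted p = 0.349), and FY of the same list was not called. The gibberellin receptor gene GID1B had 140 ± 7.12 against 202 ± 13.0 in 16-day long days, a change of -0.53 (adjusted p = 0.0309) whose call ended without Col-0 replicate 2 or 3 or flk replicate 1, 2 or 3, and GID1A and GID1C were not called. In the photosynthesis list RCA, encoding Rubisco activase, changed by -0.31 in 16-day long days and by 0.22 in continuous light, the latter not alone (adjusted p = 0.508), and LHCB4.1 was not called. PDF1.2 was the 1 measured jasmonate gene. The measured genes of the KH-domain list (PEP), the salicylic acid list (SAG101), the heat shock list (HSA32 and HSP22), the senescence list (WRKY53 and SAG101) and the shoot meristem markers (CLV3) were called in no flk comparison of 1 experiment or the average. Adjusted over the list alone, the counts were those over all probe sets, except for 2 more members of the flavonoid list and 1 more each of the jasmonate, senescence and root marker lists in 16-day long days, 1 more each of the photoperiod and root marker lists in continuous light, 1 more of the photoperiod list in 7-day long days, and 1 more each of the autonomous, cold and senescence lists in the average. No member of the lists of floral repressors, activators of floral repressors, vernalization and Polycomb genes, floral organ markers or seed markers was measured by a probe set paired with it alone. Members of these lists may be among the unnamed probe sets, which could not be assigned here.

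Within Col-0, 16-day plants collected 16 h after dawn were compared with 7-day plants collected 1 h after dawn, so age, hour and experiment changed together and could not be told apart. Intensities are given on the deposited scales, which differ. DFR, an anthocyanin synthesis gene, was higher in the older plants by 5.11 log2 units (1282 ± 77.1 against 21.1 ± 7.02), with AT3G22240 and AT5G53420 higher by 5.30 and 4.74. AT1G19960 and the beta-glucosidase gene BGLU28 were at 953 ± 38.8 and 853 ± 49.5 in the older plants and at absent-control level in the younger ones, so the sizes of their changes are not given. SWEET2, a sugar transporter gene, changed by -4.99 (41.0 ± 3.39 against 1418 ± 86.3) and HYH, a light-signalling bZIP gene, by -4.71 (17.1 ± 1.02 against 734 ± 55.4), with AT5G54130, AT2G27420 and AT5G42760 between -5.01 and -4.74. GI was higher by 1.76 ± 0.0826 (SE), COR15A by 3.32 and AGL24 by 1.22, the last 2 by 3.95 and 1.94 under the deposited scaling. In the younger plants COR15A (12.6 ± 1.51) and AGL24 (11.7 ± 1.02) lay close to the highest absent-control intensity of 10.1, so these sizes are uncertain. With arrays centred on their medians, DFR, AT3G22240 and AT5G53420 were higher by 4.23 to 4.80 and the 5 genes that were lower had changes of -5.76 to -5.15. The test called 12358 probe sets, 5761 higher and 6597 lower, or 46.6% higher. This split followed the scaling, with 67.5% higher under the deposited values and 21.3% with arrays centred on their medians, where the median over all probe sets was 0.14 and -0.54, and median centring called 19493.

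Col-0 in continuous light was compared with Col-0 in 16-day long days, where light regime, hour and experiment changed together. THI2.2 was higher in continuous light by 4.63 log2 units, and by 3.20 under the deposited scaling (787 ± 15.4 against 78.1 ± 3.43). AT1G66100, the methionine sulfoxide reductase gene MSRB6, AT1G23390 and AT2G41250 were higher by 4.46, 4.22, 4.06 and 3.90, and by 3.21, 2.84, 2.58 and 2.41 under the deposited scaling. AT5G20790, AT1G13750 and BGLU28 were lower, with changes of -4.30, -4.12 and -4.12, AT1G68600 went from 530 ± 35.9 in long days to an absent-control level of 10.5 ± 2.16, against which no size is given, and the anthocyanin glucosyltransferase gene UGT75C1 (21.5 ± 4.33 against 965 ± 29.0) changed by -3.96. Under the deposited scaling AT5G20790, AT1G13750, BGLU28 and UGT75C1 had -5.42, -4.71, -5.05 and -5.04, and with median centring -4.07 to -3.36. GI changed by -0.55 and COR15A by -1.08, and by -2.07 and -2.64 under the deposited scaling. The test called 13798 probe sets, 7059 higher and 6739 lower, or 51.2% higher, against 19.0% under the deposited scaling and 68.3% with median centring, where the median over all probe sets was -0.90 and 0.45. The filter that left out the dimmer probe sets below the median level gave 8299 calls.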

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

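The tests of spread, scaling and 5S rRNA in this part were chosen only after the results they bear on had been seen, and the counts over other splits of the arrays were planned.

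A test of the difference of the flk effect among the experiments called 1512 probe sets. The clearest named genes were THI2.2 (adjusted p = 2.97e-09), PRX52 (1.44e-08, at absent-control level in both genotypes outside 16-day long days), AT5G62720 (2.23e-08), GI (1.04e-07), AT1G66100 (1.77e-07) and AT1G62760 (3.42e-07). A gene at absent-control level in an experiment has no measurable change there, so its p-value does not by itself show that the effects differed. The cold-regulated genes COR15A (1.75e-06), COR15B (0.000417) and COR47 (0.00528) differed among experiments, with rises in 16-day long days. AGL24 had adjusted p = 0.00567, with changes of -0.63 in 16-day long days, -0.48 in continuous light and -0.035 in 7-day long days. In 7-day long days its levels lay close to the absent controls, as did those of COR15A and COR15B. The AGL24 level of flk in continuous light was also close to them (12.1 against 11.3). RCA (0.00124), DFR (0.0404) and GID1B (0.0295) had changes below 0 in 16-day long days and above 0 in continuous light. Not all of these changes were called on their own. DFR was called in neither experiment, GID1B not in continuous light, and RCA in continuous light only with the shared spread. LUMINIDEPENDENS (LD) had 0.0306, with its difference in continuous light, and the root marker EXPA18 had 0.0223, with a rise in 16-day long days. EXPA18 lay close to the absent controls in flk in continuous light (11.5 against 11.3). In 7-day long days it did so in both genotypes (13.5 and 14.7 against 10.1). Among genes named for a large change in 16-day long days, AT4G26010 (8.4e-06, at absent-control level in flk in continuous light), AT5G17820 (0.00993), rps14 (0.000374), rpoB (0.000369), JRG21 (0.00121), AT5G05600 (0.00072) and OSM34 (0.000283) differed. Among those of continuous light, AT1G70820 (3.74e-07), AT2G29670 (1.24e-06), AT5G03350 (4.83e-06), AT1G06000 (8.01e-05), AT1G13650 (0.00135), AT3G15310 (0.00135, at absent-control level in Col-0 in 7-day long days), AT1G67865 (0.00905) and AT4G31470 (0.0216) did. Among those of 7-day long days and the average, AT2G36430 (0.00165), THIC (0.00215), AtLEA4-1 (0.0176, at or close to absent-control level in both genotypes outside 7-day long days), AT3G28220 (0.0252) and petD (0.0229) did. The unnamed 250476_at (0.000538) and 261041_at (0.0108) differed in size and kept their sign in every experiment. In 100 regroupings of the arrays within experiments, the real one included, 1 gave as many calls of a difference, with 1064 as the highest of the others. For the average effect it was 1 of 100, with 1264 probe sets and 762 as the highest other. For calls of one direction in all experiments it was 1 of 100, with 12 and 0. These counts argued against genotype labels assigned by chance. Regrouping breaks up the flk effect in the experiments, so it could not test whether a real effect was equal among them. The count of differences also rests on the shared spread. For the gene lists, 37 of the 100 regroupings called as many, up to 3 lists, so chance was not excluded.

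More probe sets were called in continuous light (2645) than in 16-day long days (1024) or 7-day long days (92). Quantile normalization as the whole cause was argued against by the deposited scaling, which still called more in continuous light, 2119 against 1586, although the spread there was 0.165 as deposited and 0.213 after normalization. Unequal spread between experiments was a candidate explanation that the numbers bore out, since fits of each experiment alone called 114 in continuous light and 4771 in 16-day long days. Larger and smaller effects of the flk genotype in continuous light could not be told apart, because the SD of the changes beyond replicate noise was 0.138 there, from 0.0716 to 0.200 with single arrays left out, against 0.165 in 16-day long days. With 10 splits of 6 arrays no share under 0.05 can arise; 1 split gave as many calls in each experiment, the real one, and the highest other gave 0 in 16-day and 7-day long days but 2556 in continuous light, where Col-0 replicate 1 joined flk replicates 1 and 2, the arrays with the highest actin 3'/5' ratios (2.57, 2.38 and 1.97 against 1.38, 1.38 and 1.82), so a structure of the arrays that followed this sign of RNA quality, though not the GAPDH or ubiquitin ratio, stayed open.

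Both comparisons within Col-0 had the same 10 splits, of which 1, the real one, gave as many calls, 12358 for age and hour and 13798 for light, against 0 for every other split.

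The 5S rRNA control probe set, used in no comparison, had an intensity of 75.4 ± 3.51 in flk and 24.9 ± 1.24 in Col-0 in 16-day long days. General carryover of RNA without a poly(A) tail was argued against by the 69 plastid-encoded probe sets, whose changes had a 75th percentile of 0.24 against 1.33 for 5S rRNA. Of the 69, 6 were called higher and 4 lower. Among those higher, rps14, rpoB and petD rose by 1.51, 1.31 and 1.13, near the 5S rRNA value, so the argument does not extend to these transcripts. More degraded RNA in flk was argued against by the 3'/5' ratios of actin, GAPDH and ubiquitin, of which the highest difference was -0.0135. An effect of the flk genotype stayed open. In 7-day long days the difference was 0.15 (126 ± 34.0 against 110 ± 6.87) and the arrays overlapped. In continuous light it was 0.12, with all flk arrays (12.52 to 15.76) above all Col-0 arrays (11.53 to 12.35). These levels lay close to the highest absent-control intensity there of 11.3, too dim to decide. No test addressed how the RNA was labelled.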

How the results depend on the processing

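Weights per experiment and the average over the long-day experiments were chosen only after the results were seen, and all other alternatives were planned.

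Of 291 named-gene values, recomputed 8261 times, 7818 kept direction and side of the threshold, 183 lost the call, 115 gained one and 145 turned sign, 22 of them with a call in at least 1 of the compared fits. For counts moved over 1.5 times, the deposited scaling gave 1586 in 16-day and 197 in 7-day long days. Median centring gave 1572 and 237, and 19493 for age and hour. The filter at the median gave 8299 for light in Col-0. Each experiment alone gave 4771 in 16-day long days, 114 in continuous light, 320 in 7-day long days and 4 called in all. Array weights gave 5108, 484, 898 and 20 in that order. Weights per experiment gave 4987, 173 and 665, and 566 for the difference among experiments. The long-day average gave 3240. At least 2-fold left 70, 29 and 4, and adjusted p under 0.01 left 565, 1007 and 30, fewer by construction. For gene lists, an estimated correlation left 0 and fry gave 4 in place of 1, and no list kept 4 genes under the filter at the median, so none was tested. The cause of the other shifts was not tested.

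Leaving out single arrays gave 630 to 1518 in 16-day long days, 1773 to 5457 in continuous light, 29 to 216 in 7-day long days, 843 to 2741 for the average, 1018 to 3634 for the difference, 5 to 24 in all experiments, 1 to 2 for gene lists (2 without flk replicate 1 of continuous light), 11100 to 13371 for age and hour and 12427 to 14276 for light. Without any 1 of the 6 arrays of 16-day long days, that count was 630 to 670, and Col-0 replicate 1 of continuous light gave the maxima of 5457, 216, 2741 and 3634.

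Among values with such a call, signs turned under the deposited scaling for FY (0.29 by age, -0.77 by light), PEP (0.21, -1.42) and EXPA7 (0.29, -0.029), and by light for SAG101 (-0.61), COR15B (-0.77), HSA32 (-0.29), RCA (-0.46) and EXPA18 (-0.53). Under median centring they turned for AGL42 (-0.45 by age, 1.28 by light), AGL19 (-0.57, 1.40) and WRKY53 (-0.14, 0.63), by light for FD (0.22) and by age for PYK10 (-0.35) and CLV3 (-0.51). Over long days alone the averages of GI (0.25) and COR15B (0.50) turned. The deposited scaling and median centring move all genes between experiments.

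The other 123 turns concerned values called with neither sign. Under the deposited scaling this was so in 16-day long days for GID1C (-0.0035), LHCB4.1 (-0.011) and PYK10 (-0.0030), in continuous light for AT1G66100 (0.020) and LHCB4.1 (-0.023), in 7-day long days for FD (-0.0053), AGL19 (-0.0036), LUMINIDEPENDENS (0.0095) and HSP22 (-0.0071), on average for FD (-0.011), by age for HSP22 (0.027) and by light for AGL19 (0.044). With median centring it was so in 16-day long days for LUMINIDEPENDENS (0.0085), in continuous light for AT1G66100 (0.0022) and LHCB4.1 (-0.040), in 7-day long days for AGL42 (-0.014), FD (-0.020), AGL19 (-0.019) and HSP22 (-0.022), on average for FD (-0.014), by age for EXPA18 (-0.13) and by light for PEP (-0.064). With array weights it was so in continuous light for GID1A (-0.033), in 7-day long days for FD (-0.0086), AGL19 (-0.022), LUMINIDEPENDENS (0.016), GID1B (-0.0058) and EXPA18 (0.019), on average for COR15B (0.093) and 5MAT (0.032) and by light for EXPA18 (-0.050). Over long days alone it was so on average for FD (-0.0077), LUMINIDEPENDENS (-0.0088), PEP (-0.046), HSA32 (-0.0086), HSP22 (0.028), DFR (-0.091) and CLV3 (0.014).

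Leaving out single arrays accounted for 85 of these 123 turns, of 40 values, whose ranges over all arrays left out crossed 0. In 16-day long days they were -0.026 to 0.045 for GID1C, -0.070 to 0.034 for LUMINIDEPENDENS, -0.0046 to 0.063 for PEP, -0.043 to 0.085 for LHCB4.1 and -0.057 to 0.014 for AGL42. In continuous light they were -0.083 to 0.057 for PRX52, -0.057 to 0.034 for AGL19, -0.087 to 0.11 for GID1A, -0.11 to 0.43 for GID1C, -0.022 to 0.28 for SAG101, -0.065 to 0.040 for AT1G66100, -0.54 to 0.045 for CLV3 and -0.40 to 0.089 for UF3GT. In 7-day long days they were -0.028 to 0.070 for FY, -0.020 to 0.063 for GID1B, -0.096 to 0.026 for COR15A, -0.040 to 0.099 for FD, -0.031 to 0.032 for AGL19, -0.056 to 0.037 for LUMINIDEPENDENS, -0.12 to 0.0021 for COR15B, -0.035 to 0.073 for HSP22, -0.11 to 0.040 for UGT75C1, -0.058 to 0.052 for 5MAT, -0.086 to 0.028 for WRKY53, -0.14 to 0.057 for EXPA18, -0.018 to 0.11 for COR47 and -0.0095 to 0.056 for AGL42. For the average they were -0.070 to 0.030 for SAG101, -0.13 to 0.082 for COR15B, -0.14 to 0.0014 for GID1B, -0.0046 to 0.18 for GID1C, -0.12 to 0.065 for 5MAT, -0.17 to 0.024 for CLV3, -0.021 to 0.048 for FY, -0.082 to 0.0043 for HSP22, -0.0036 to 0.11 for EXPA7, -0.065 to 0.087 for EXPA18 and -0.0062 to 0.067 for PEP. By light they were -0.066 to 0.011 for AGL19 and -0.39 to 0.12 for PDF1.2.

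No clear pairing by replicate number was seen. Same-numbered arrays correlated at -0.102 to 0.171, 2 of 9 pairs over 0.1, and 4 Col-0 arrays correlated best with their own number. These 9 values could not exclude a weak pairing. With the number as a block, counts were 1021, 2883 and 69 in the 3 experiments, 1365 for the average and 1423 for the difference, none moved over 1.5 times.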

Other observations

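The families of probe sets and the plastid set were formed after the data were seen, while the tests of the FLK neighbourhood and of age were written down before their results.

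Plastid-encoded genes moved unevenly in flk in 16-day long days. Of 69 measured probe sets, 6 rose and 4 fell, rps14 by 1.51, rpoB by 1.31 and petD by 1.13 among those that rose, and the median change was 0.09. In the same arrays the 5S rRNA control probe set rose by 1.33 on the deposited scale, and a shared origin was not tested. Their shift as a set had camera adjusted p = 0.290 (adjusted p = 0.973 with an estimated correlation) among 120 pairs of 30 gene families and 4 comparisons. The 8 autophagy (ATG) genes had a median change of 0.18 in 7-day long days with adjusted p = 0.00139, which was lost with an estimated correlation (adjusted p = 0.801 with an estimated correlation), and 0 of them were called.

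One hypothesis was that sequence linked to the FLK locus differs between flk and Col-0 and that genes near it would be called more often. Among 89 measured genes within 100 genes on each side of FLK, 6 were called in the average effect (6.74%), against 686 of 13197 elsewhere (5.20%). The odds ratio was 1.32 with a 95% interval of 0.469 to 3.01 and Fisher's exact p = 0.469 (two-sided), so these data left open whether linked differences may contribute.

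A second hypothesis was that flk in continuous light may resemble younger plants, tested with the 200 genes highest and the 200 lowest in Col-0 at 16 days against 7 days, from arrays outside the continuous-light experiment. The genes that rose with age were lower in flk (median -0.15, 136 of 200 lower, adjusted p = 0.0203 in camera with an estimated correlation), and the genes that fell with age were higher (median 0.18, 148 of 200 higher, adjusted p = 0.00012). With continuous light fitted alone the adjusted p-values were 0.0605 and 0.00937, so the first was not past the threshold. The median gap between the sets was 0.33 in the real split and up to 0.21 in the other 9 splits of the 6 arrays. The split with 0.21 set the 3 arrays with the highest actin 3'/5' ratio against the other 3, and the mean ratio was also higher in flk (2.05 ± 0.289 against 1.77 ± 0.687), so a contribution of RNA quality to this shift was not excluded. Age was confounded with hour of collection, so the data would be as much in line with a shift of the daily phase, and this was not separated.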
